A study of Bos taurus with 8 samples.

How the data were processed

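RNA of cattle embryos flushed from the uterus on day 6 after insemination was compared between Holstein and Jersey on 8 two-colour EmbryoGENE arrays, each carrying both breeds. Per the labels, donors were superovulated with 400 mg of FSH in total after follicles over 8 mm were aspirated, received 500 µg of a prostaglandin analogue with each of the last injections and were inseminated with pooled semen. Per the labels' protocols, RNA was extracted with a PicoPure kit, amplified in 2 rounds with T7 polymerase and labelled with Cy3 or Cy5 by the ULS chemistry. The stated design has 4 replicates per breed, each hybridised in both dye orientations. Neither the number of embryos or donors in a replicate, nor the scanner and its quantification software, is given in the sources used here, so the spread between replicates may be that of technical or of biological repeats.

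The deposited scanner files give each spot's foreground and local background as a raw intensity at 532 nm (Cy3) and 635 nm (Cy5), with no background correction. One further deposited column is of the kind other: a mark of 0 or 1 for spots ignored at quantification, set on 131 spots over all arrays. The deposited value table holds a log2 ratio per probe and array, centred near 0, whose steps the authors do not state. Set against the scanner files, its sign was Jersey over Holstein on all 8 arrays, and it was used only as an alternative source. All per-sample columns used were assigned to an array, leaving 0 unassigned.

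Values were recomputed from the scanner files in R 4.3.3 with limma 3.58.1. Mean foreground was corrected for the median local background with normexp (offset 50), and log ratios were normalized by loess within each array, with control and ignored spots at weight 0 and no step between arrays. Each array had 45220 spots, of which 43794 were single probes and 1426 were control or other spots. A probe was kept when it exceeded the mean plus 2 SD of the 153 negative control spots for either breed on at least 4 of the 8 arrays, which left out 11665 probes as too dim. The deposited probe annotation gave 1 gene symbol to 21790 probes and none to 22004. Of the former, 20068 matched the RefSeq annotation of the assembly ARS-UCD2.0 by symbol, 1644 by a synonym and 78 not at all. The annotation served for names and chromosomes alone. Of 32129 probes kept, 16744 had a symbol, for 12347 genes, and 15385 had none.

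The labels do not say which arrays form a dye-swap pair. Among the 24 matchings of opposite orientation, the one with the highest sum of correlations of residuals was taken. Its pairs correlated at 0.46 to 0.71 across probes, against -0.36 to -0.02 for all other combinations, and were neighbouring arrays on a slide. Each residual was a log ratio minus the mean of its orientation, which pushes other combinations below 0 once the chosen ones are above it. The matching was also picked for this sum, so the contrast does not test whether the pairs are right. Probes are not independent replicates. The 2 arrays of a pair were averaged, which cancels the dye effect, and the 4 pair means of log2(Holstein / Jersey) were tested against 0 with limma (lmFit, eBayes) and Benjamini-Hochberg adjustment at 0.05. Beside it stands a fit of 8 arrays with a dye term and the pair as a random block, an alternative that weighs arrays singly. It covers 32033 probes and found a consensus correlation of 0.31 within pairs. That 1 value served for all probes, so probes whose dye swaps agree but whose pairs differ can pass too easily. Errors are moderated SE over 4 pairs.

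Gene lists of 20 pathways and 10 cell types were tested with camera (correlation preset at 0.01, and estimated) and fry from limma where at least 5 genes were measured, by the brightest probe of each gene. Genes are named by a rule: in each direction the 10 largest changes past the threshold or, where fewer than 5 passed, the 5 genes of smallest p; the 3 smallest p of each list; and all measured Y-linked genes and XIST. ACSL1, HSD17B4, SDHD, NDUFS1 and PDK3, which passed over their list alone or with the random block, ALAS2, the genes that differed between slides and those with the largest differences were named after their values were seen. The dye effect and the difference of the breed effect between slides were tested on 8 arrays. The tests, the lists, the rule, the filter and most alternatives were fixed before the data were examined. Those fixed later are the chromosome comparison, the largest differences, the share of probes without a symbol, the limit to splits that treat pairs as the real one does, normexp against the negative controls, leaving out X-linked genes, each slide alone, and the printing of a named gene's mean without 1 pair where it moves over 1.5 times. Alternatives covered background correction, normalization, dim probes, replicates, pairing, slide, the variance prior, the value source, each pair left out, thresholds, the probe per gene and the set test.

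The procedure was tested on simulated data with 32033 probes, of which 200 changed. In 10 runs the pair-mean fit recovered 20.4% of changes of 1.5-fold, 73.4% of 2-fold, 96.4% of 3-fold and 98.0% of 4-fold, with 5.31% of calls false. The random-block fit recovered 53.3%, 80.0%, 97.3% and 98.7% in 3 runs, with 3.81% false. Arrays as independent samples gave 14.4% false calls. The true pairs were found in 10 of 10 runs. A list of 40 genes shifted by 0.5 was found in 10 of 10 runs, and 0 of 190 unshifted lists were called. Simulated probes were independent of each other, with a common pair correlation of 0.31 and no deviating pair. Measured lists had estimated correlations up to 0.31, and the shift of 0.5 was larger in size than any list median found. These rates therefore need not hold for the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.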

Results

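Transcript levels of day 6 Holstein and Jersey embryos were measured together on 8 arrays, 4 with Holstein in Cy5 and 4 with Jersey in Cy5, on 2 slides of 4 arrays. The labels describe Holstein embryos as tolerating cryopreservation well and Jersey embryos as doing poorly after freezing, and the comparison asks which transcripts differ between them. Median spot intensity was 171 to 265 in Cy5 and 230 to 316 in Cy3, against means of 128 to 212 and 172 to 253 over the negative control spots. Between 41.7% and 63.2% of probes lay above background in Cy5, and between 42.8% and 80.8% in Cy3. At most 34 spots of an array reached the scanner ceiling. The number of arrays limits the precision.

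XIST, the X-linked RNA that silences an X chromosome in female cells, was 7.63-fold higher in Jersey embryos. Its log2(Holstein / Jersey) was -2.93 ± 0.35 (SE, n = 4 pairs), below 0 on 8 of 8 arrays. Genes elsewhere on the X chromosome were also lower in Holstein, with a median of -0.15. Among the genes of smallest p, the mitochondrial phosphatase PPM1K and methylmalonyl-CoA mutase, MMUT, were higher in Holstein. The sugar-phosphate mutase PGM2, the AMP-activated kinase subunit PRKAG2 and the antiviral membrane protein IFITM3 were higher in Jersey. None of these genes passed the adjusted threshold on pair means, and all of those named here passed it with the pair as a random block. The second fit uses the same arrays, and all 1209 of its calls had an unadjusted p under 0.05 on pair means. Passing it is therefore no separate support for genes picked by a small p.

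On pair means, limma found 0 of 32129 probes past the threshold, with a smallest adjusted p of 0.0679. An unadjusted p under 0.05 was reached by 4482 probes, 2125 higher in Holstein and 2357 higher in Jersey, against 1606 by chance. With the pair as a random block 1209 of 32033 probes passed, 524 higher in Holstein and 685 in Jersey, for 626 named genes. Of these 1209 probes, 1195 had the same direction in all 4 pairs and 934 on all 8 arrays. Choosing probes by a small p over the same arrays favours such agreement, so it is no separate support. Restricting the test to the 14019 probes above background in both channels of all 8 arrays left 48 past the threshold on pair means, 5 higher in Holstein and 43 in Jersey, among them PPM1K, TMEM254, XIST, BCAP31, PGM2, IFITM3 and GIMAP4.

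Higher in Holstein, 5 genes head the list by p among probes with a gene name. They had an adjusted p of 0.0738 or 0.0739 and the same direction on 8 of 8 arrays. PPM1K (probe EMBV3_36856, chromosome 6) was 2.23-fold higher, a log2 ratio of 1.15 ± 0.09. METTL21A (EMBV3_00048, chromosome 2), a methyltransferase of heat shock protein 70 family members, had the ratio 1.64 ± 0.15. Its Jersey signal was above background on 3 of 8 arrays, so the size of the ratio depends on the floor. Of the 3 METTL21A probes, 1 went the other way at -0.24. TMEM254 (EMBV3_34239, chromosome 28) was at 0.96 ± 0.08, while its second probe stood at -0.02. MMUT (EMBV3_39055, chromosome 23) had a ratio of 0.81 ± 0.07 and the Golgi mannosidase MANEA (EMBV3_09587, chromosome 9) one of 0.78 ± 0.07.

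In Jersey, the corresponding 5 genes had an adjusted p of 0.0738, again with 1 direction on 8 of 8 arrays. PGM2 (EMBV3_11009, chromosome 6) stood at -1.29 ± 0.11, 2.44-fold higher in Jersey, and PRKAG2 (EMBV3_39515, chromosome 4) at -1.05 ± 0.09. BCAP31 (EMBV3_32173, chromosome X), a chaperone of the endoplasmic reticulum membrane, had a ratio of -0.999 ± 0.07. IFITM3 (EMBV3_22748) had -0.93 ± 0.07, and monoamine oxidase MAOB (EMBV3_21464, chromosome X) had -0.81 ± 0.07.

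**Figure D1:**
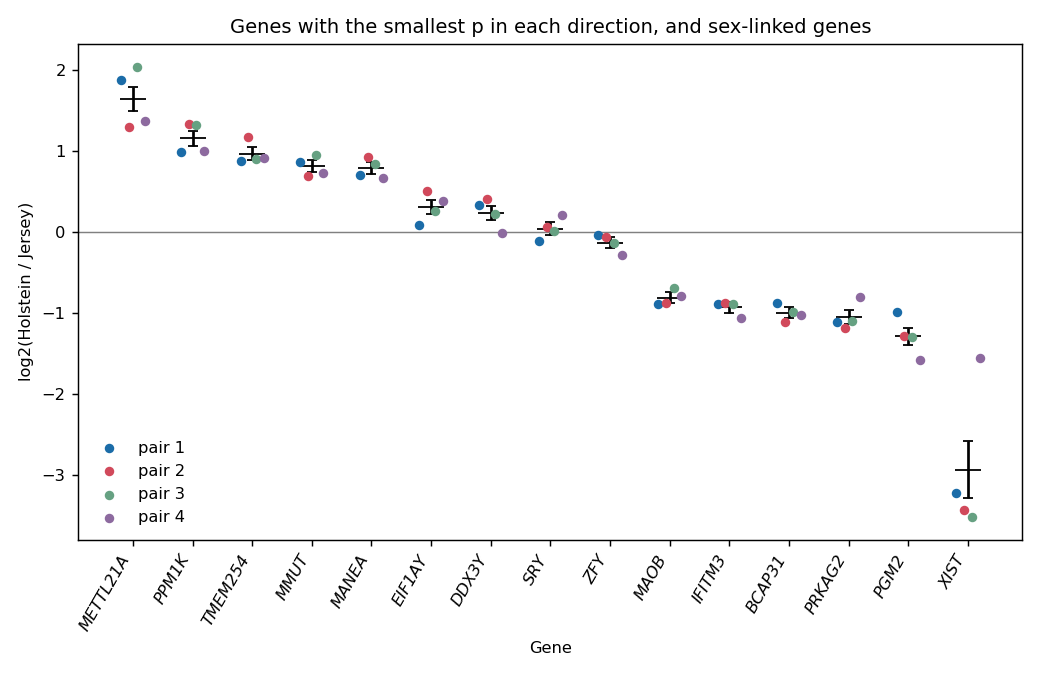
Log2(Holstein / Jersey) of the 5 genes of smallest p in each direction and of the sex-linked genes measured. Points are the 4 dye-swap pairs and bars the mean with its moderated SE. XIST lies at -3.52 to -1.56 in the pairs, while the Y-linked genes, near the detection floor, lie between -0.29 (ZFY) and 0.51 (EIF1AY).

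Lipid genes, the group closest to the cryotolerance named in the labels, did not move together. Of 30 genes of lipid droplets and triglyceride storage, 14 were higher in Holstein and 16 in Jersey, with a median of -0.04 (camera adjusted p = 0.971). Adjusted over the list alone, with no adjustment across the 30 lists, 4 passed. Over all kept probes their adjusted p was 0.134 to 0.169. The acyltransferases SOAT1 (0.53 ± 0.09), which makes cholesteryl esters, and GPAM (0.52 ± 0.10), which begins triglyceride synthesis, and the acyl-CoA synthetase ACSL1 (0.45) were higher in Holstein. The X-linked acyl-CoA synthetase ACSL4 (-0.42 ± 0.08) was higher in Jersey, and the same 4 passed with the pair as a random block. Of 13 lipolysis genes 9 were higher in Holstein and none passed in either fit; LIPA, the lysosomal acid lipase, was at 0.24 ± 0.07, PNPLA6 at 0.27 ± 0.10 (0.15 without pair 3) and DDHD2 at -0.27 ± 0.12, though the other 2 probes of DDHD2 were above 0, up to 0.34.

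Fatty acid oxidation and carnitine genes divided evenly, with 21 of 40 higher in Holstein, yet 8 of the 10 with an unadjusted p under 0.05 were higher there. Adjusted over the list alone 4 passed: medium-chain acyl-CoA dehydrogenase ACADM (0.49 ± 0.10), the peroxisomal enzyme HSD17B4 (0.44) and the peroxisomal transporter ABCD3 (0.43 ± 0.07) in Holstein, and the X-linked mitochondrial dehydrogenase HSD17B10 (-0.74 ± 0.09) in Jersey. With the random block 5 passed, 3 higher in Holstein, and HSD17B4 did not (adjusted p = 0.0626). Of 32 fatty acid synthesis and desaturation genes, 15 were higher in Holstein and none passed in either fit. Fatty acid synthase FASN was at 0.59 ± 0.21, higher in Holstein in 3 of 4 pairs, and OXSM at 0.20 ± 0.07. The desaturase FADS1 was at -0.51 ± 0.18 (-0.31 without pair 2), while its second probe stood at -0.01.

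Among 23 cholesterol synthesis genes, 14 were higher in Holstein, with a median of 0.08 (camera adjusted p = 0.847). The isomerase IDI1 (0.60 ± 0.11) and the sterol sensor partner SCAP (-0.46 ± 0.11) passed with the random block, in opposite directions, and SC5D stood at 0.36 ± 0.09. The 38 phospholipid and sphingolipid genes were 19 higher in each breed, with SPTLC1 at 0.42 ± 0.11, its direction seen on 5 of 8 arrays. Among the 3 past the threshold with the random block were CDIPT (-0.42 ± 0.08, its second probe at -0.06) and LPCAT4 (0.68 ± 0.18). Of 29 lipid uptake and transport genes 16 were higher in Holstein, and 2 passed adjusted over the list alone, the lysosomal cholesterol carrier NPC1 (0.46 ± 0.08) and GOT2 (0.46 ± 0.09), of which NPC1 did not pass with the random block (adjusted p = 0.0826). SCP2 was at -0.41 ± 0.13, though 3 of its 4 probes were above 0, up to 0.41.

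In oxidative phosphorylation 36 of 75 genes were higher in Holstein, with a median of -0.02 and a mean of 0.02, so that the sign differed (camera adjusted p = 0.971). Adjusted over the list alone 5 passed: SDHD (0.64), NDUFA3 (0.71 ± 0.10) and NDUFS1 (0.48) in Holstein, and the X-linked complex I subunits NDUFA1 (-0.84 ± 0.10) and NDUFB11 (-0.96 ± 0.11) in Jersey. All 3 X-linked members had an unadjusted p under 0.05 and were higher in Jersey. Median centring in place of loess turned this list's median to 0.13 and that of 63 ribosomal protein genes from -0.02 to 0.15, with camera adjusted p of 0.0024 and 0.000533. With an estimated correlation both had an adjusted p of 0.866. Of those ribosomal genes 24 were higher in Holstein, and RPL39 (-0.72 ± 0.11, X-linked) passed with the random block, while FAU stood at 0.43 ± 0.13 (0.28 without pair 3) and RPLP1 at 0.24 ± 0.07. Of 35 genes of mitochondrial upkeep and shape 22 were higher in Holstein, with a median of 0.08 (camera adjusted p = 0.610). TFB1M was at 0.38 ± 0.08, SSBP1 at 0.34 ± 0.08 and OPA1 at 0.34 ± 0.10, its 3 probes running from 0.01 to 0.59. SSBP1 had its direction on 5 of 8 arrays.

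Glycolysis and pentose phosphate genes leaned to Jersey, with 23 of 36 higher there and a median of -0.08, though the list did not pass (camera adjusted p = 0.195). Glucose-6-phosphate isomerase GPI (-0.65 ± 0.16) and the X-linked pyruvate dehydrogenase genes PDHA1 (-0.44 ± 0.10) and PDK3 (-0.96) passed with the random block, and PDK2 was at -0.44 ± 0.12. One of the 3 PDHA1 probes stood at 0.17. Of 38 antioxidant genes 23 were higher in Jersey (median -0.05). Mitochondrial superoxide dismutase SOD2 (0.59 ± 0.13) was higher in Holstein and passed in that fit, with NFE2L2 at 0.45 ± 0.12 and PRDX4 (X-linked) at -0.75 ± 0.23. NFE2L2 had its direction on 5 of 8 arrays, and was at -0.18, -0.20 and -0.44 on the others, all with Jersey in Cy5.

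Heat shock and endoplasmic reticulum stress genes were higher in Jersey for 28 of 42 members, with a median of -0.12. The small heat shock protein HSPB1 stood at -1.12 ± 0.30, 2.18-fold higher in Jersey on 8 of 8 arrays, and passed with the random block. DDIT3 was at -0.73 ± 0.23. DNAJB1 was at -0.34 ± 0.09, but below 0 only on the 4 arrays with Holstein in Cy5. The highest of the 3 DNAJB1 probes stood at -0.005. The list missed the threshold (camera adjusted p = 0.122, and adjusted p = 0.982 with an estimated correlation). It passed with slide as a term (adjusted p = 0.035) and without replicate 1 (0.00758), but with an estimated correlation the adjusted p was 0.961 and 0.915. Over its alternatives the preset correlation gave 0.00758 to 0.679, and the median was -0.04 without replicate 2.

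Other pathway lists also missed the threshold. Apoptosis and p53 genes were 13 higher in Holstein and 15 in Jersey, with CASP9 at -0.48 ± 0.13 (1 of its 3 probes at 0.03). AIFM1 was at -0.32 ± 0.10 and FADD at -0.32 ± 0.09, the latter with its direction on 4 of 8 arrays. Aquaporin, ion transport and junction genes were 18 and 19, with the water and glycerol channel AQP3 at -0.49 ± 0.13, TJP1 at 0.39 ± 0.11 and PARD6B at -0.43 ± 0.12. Methylation and imprinting genes leaned to Jersey, with 14 of 22 higher there and a median of -0.10 (camera adjusted p = 0.367), and SGCE (-0.54 ± 0.07), imprinted in mammals, passed adjusted over the list alone, beside TET3 at -0.55 ± 0.15 and ZFP57 at 0.31 ± 0.09. The 23 interferon response genes had 13 members higher in Jersey, with IRF3 at -0.29 ± 0.10, STAT2 at 0.24 ± 0.08 and IRF9 at -0.20 ± 0.08. IRF3 and IRF9 each had their direction on 5 of 8 arrays. Of 13 MHC class I genes 8 were higher in Jersey (median -0.11, mean 0.02), and the peptide-loading protein TAPBP (-0.53 ± 0.09) passed adjusted over the list alone, with ERAP1 at 0.70 ± 0.18 and NLRC5 at 0.30 ± 0.10. Jersey signal was above background on 3 of 8 arrays for ERAP1, NLRC5 and ZFP57, so the size of these ratios depends on the floor. Cell cycle genes were 21 higher in Holstein and 28 in Jersey, with E2F1 at -0.35 ± 0.09, TK1 at -0.32 ± 0.09 and MCM7 at -0.33 ± 0.10. Proteasome genes were 21 and 16, with PSMC6 at 0.35 ± 0.07 (its second probe at 0.09). PSMD10 (X-linked, -0.74 ± 0.15) and PSMC4 (-0.37 ± 0.08, its second probe at -0.05) passed with the random block.

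Lineage markers differed singly. Of 20 inner cell mass markers 15 were higher in Jersey, with a median of -0.17, but the list did not pass (camera adjusted p = 0.195); KLF17 stood at -0.30 ± 0.08, SALL4 at -0.30 ± 0.08 and ARGFX at -0.86 ± 0.46 (-0.40 without pair 2 and -1.35 without pair 4). Of 18 primitive endoderm markers, PDGFRA (0.77 ± 0.10, 1.70-fold) and GATA4 (0.50 ± 0.10) were higher in Holstein and passed adjusted over the list alone, whereas the matrix protein SPARC (-1.07 ± 0.32, and -0.70 without pair 3) was higher in Jersey. All 3 passed with the random block. The lowest of the 3 PDGFRA probes stood at 0.08. Of 30 trophectoderm markers 19 were higher in Holstein, with a median of 0.08, while the pair medians ranged from -0.35 to 0.19; KRT7 was at -1.07 ± 0.38 (-2.56 in pair 2 and -0.62 to -0.52 in the others) and DAB2 at 0.39 ± 0.15 (2 of its 4 probes below 0, down to -0.14). Of 29 maternal oocyte genes 16 were higher in Holstein, with the germ cell genes DDX4 at -0.88 ± 0.28 and SYCP3 at -0.93 ± 0.30 (-0.58 without pair 2). NLRP5 was at -0.31 ± 0.07, with its direction on 4 of 8 arrays and Holstein above background on 3 of 8. Of 9 genome activation genes, NFYA (0.76 ± 0.12) and KLF17 passed adjusted over the list alone; KLF17 had its direction on 4 of 8 arrays and did not pass with the random block (adjusted p = 0.0902). ZSCAN4 was at -0.31 ± 0.10. The second probe of NFYA stood at 0.03.

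Markers of other cells that flushing could bring along did not pass as lists. Erythrocyte markers had a median of -0.37 over 8 genes, and of -0.13 over 7 without the X-linked ALAS2 (camera adjusted p = 0.603 and 0.585), with the globins HBG at -1.94 ± 0.91, HBB at -1.0 ± 0.45 and HBA at -0.60 ± 0.19. HBG was at -4.22 and -3.84 in the pairs of the first slide and at 0.13 and 0.16 in those of the second, and HBB at -2.24 and -1.79 against -0.02 and 0.05. With slide as a term the list passed (adjusted p = 0.035, but adjusted p = 0.961 with an estimated correlation). Of 12 leukocyte markers 8 were higher in Jersey, with CD3E at -0.27 ± 0.09, PTPRC at -0.16 ± 0.09 and LYZ1 at -0.49 ± 0.36 (-0.10 without pair 2 and -0.83 without pair 1), its other probe being at 0.86. The 15 cumulus and granulosa markers had 8 members higher in Holstein. INHBA was at 0.79 ± 0.24 and CYP19A1 at 0.54 ± 0.12, the lowest of its 3 probes being at 0.07. NR5A2 was at -0.43 ± 0.15 (-0.27 without pair 2), though 2 of its 3 probes were above 0, up to 0.27. Uterine epithelium markers were 5 and 5, with OVGP1 at -0.22 ± 0.09 (-0.14 without pair 1), MEP1B at 0.15 ± 0.08 and PIGR at 0.12 ± 0.06, and 5 of 7 sperm markers were higher in Holstein, with ODF2 at 0.49 ± 0.15, HSPA1L at 0.17 ± 0.07 and TNP1 at 0.43 ± 0.21 (0.17 without pair 3). For ODF2 and HSPA1L, Jersey was above background on 3 of 8 arrays. HSPA1L had its direction on 4 of 8 arrays, and MEP1B and LYZ1 each had theirs on 5 of 8.

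In all, 0 of the 30 lists passed with camera or with fry's test of direction, and every list had an adjusted p of 0.982 with an estimated correlation. Leaving out X-linked genes also gave 0 lists. Many lists changed in either direction by fry's mixed test, such as primitive endoderm (adjusted p = 0.000332), oxidative phosphorylation (0.00134) and lipid droplets (0.00211). Maternal oocyte genes (0.0177), ribosomal proteins (0.0197) and the proteasome (0.0243) were among them too. That test does not compare a list with other genes, so it marks none of these lists as particular.

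**Figure D2:**
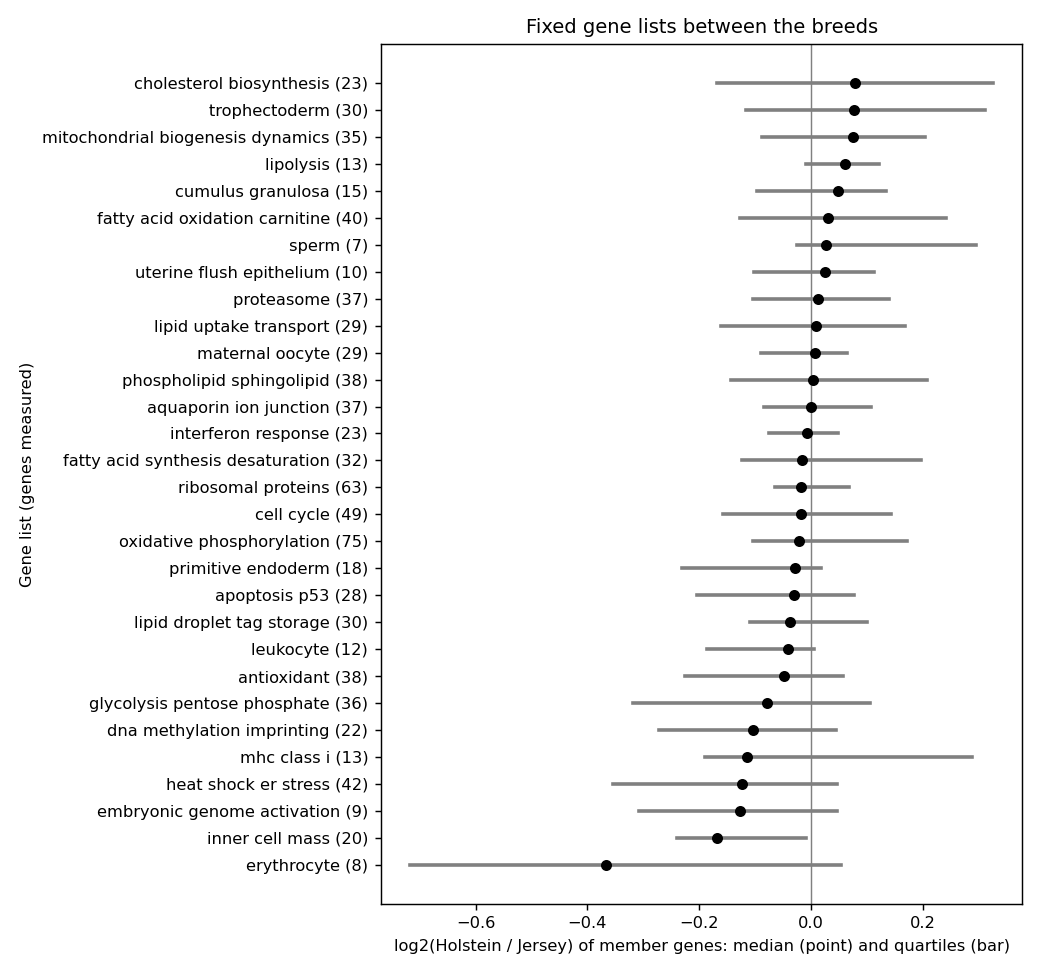
Median (point) and quartiles (bar) of log2(Holstein / Jersey) over the measured genes of each fixed list, with the number of genes in brackets. Medians lie between -0.37 (erythrocyte, -0.13 without its X-linked gene) and 0.08 (cholesterol biosynthesis), and no list passed camera; median centring turns oxidative phosphorylation and ribosomal proteins above 0.

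X-linked genes stood apart from the other chromosomes, a comparison chosen after the values were seen. Without XIST, 401 of 544 X-linked probes (73.7%) were higher in Jersey, against 46.1% of 16064 autosomal probes. Autosomes had medians between -0.04 and 0.06. Of the X-linked probes, 185 higher in Jersey and 10 higher in Holstein had an unadjusted p under 0.05, and 90 and 2 passed with the random block. Taken as a list of 442 genes, they had a camera p of 2.13e-15 with the preset correlation and p = 0.0394 with an estimated correlation of 0.061. None of 10000 random lists of probes of matching intensity had as low a median, the lowest being -0.01. Randomly drawn probes need not share the correlation of 0.061 among X-linked genes, so medians of such lists can spread too little. The draw therefore does not test whether the X-linked shift exceeds the spread between pairs. XIST had an adjusted p of 0.0885 on pair means and 0.000795 with the random block. Y-linked genes lay near the detection floor. EIF1AY was at 0.31 ± 0.09 (adjusted p = 0.244), DDX3Y at 0.23 ± 0.09 (0.358), SRY at 0.04 ± 0.08 (0.897) and ZFY at -0.13 ± 0.07 (0.508), and TSPY was not kept.

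**Figure D3:**
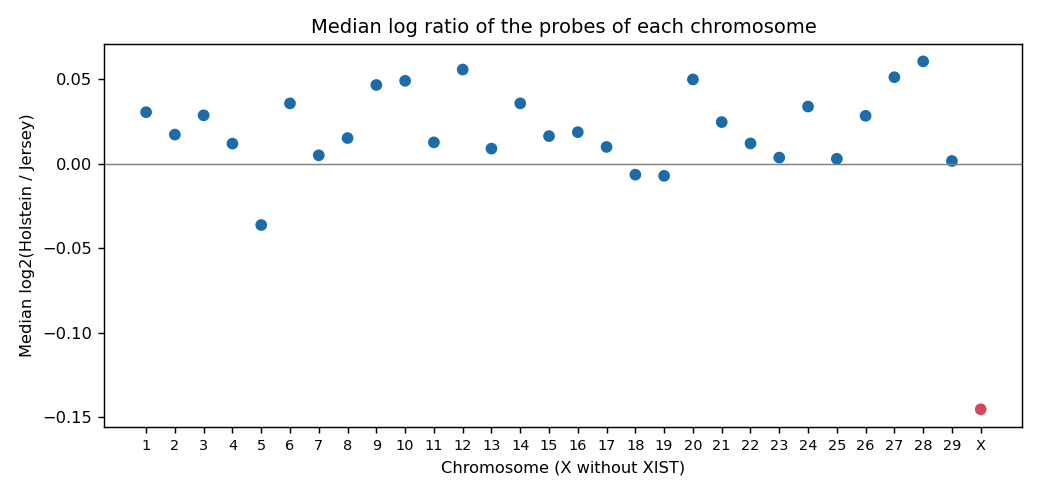
Median log2(Holstein / Jersey) of the kept probes of each chromosome, X without XIST. The X chromosome lies at -0.15, below the autosomes at -0.04 to 0.06.

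The breed difference varied between the slides for 24 of 32033 probes on 8 arrays, 13 of them with a symbol, and for 12 with the pair as a random block. The fit of 8 arrays counts both arrays of a dye-swap pair as separate samples. Its p-values therefore rest in part on the spread between dye swaps, and can be too small for a difference between replicates. Each pair lay on a single slide, so a slide difference cannot be told apart from a difference between replicates. Other groupings of whole pairs differed in up to 130 probes. Besides HBG (adjusted p = 3.12e-05) and HBB (0.0116), the probes that differed on 8 arrays included CD68, a macrophage marker, at -1.29 on the first slide and 0.45 on the second. The ribosome assembly factor RSL24D1 was at -0.29 and 1.98. Its second probe, at -0.29 and 1.14, did not pass with the random block (adjusted p = 0.0773). A dye effect was found for 5400 probes, 2197 brighter in Cy5 and 3203 in Cy3, which averaging over both orientations removes from the breed difference.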

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

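The tests of XIST and of the X chromosome, and the limit to splits that keep each pair whole, were chosen only after the result was seen; those of the fourth pair were not.

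XIST stood at -3.22, -3.43 and -3.52 in the first 3 pairs and at -1.56 in the fourth, which lay apart from the others. X-linked genes without XIST lay below autosomal genes by a median of -0.16, -0.16, -0.21 and -0.08 in the same pairs. A dye bias is excluded, since the mean XIST ratio was at or below -2.93 in both orientations and the X-linked median was below the autosomal one on all 8 arrays. A breed variant under the XIST probe could not shift the other X-linked probes, whose shift in the pair nearest to 0 was -0.0794. It cannot account for them whatever their values, so they do not test it. For XIST itself, which has 1 probe, such a variant cannot be told apart. A larger share of female embryos in the Jersey replicates is a candidate explanation: the mean X-linked shift of -0.153 was below 0 in 4 of 4 pairs and was nearest to 0 in the pair with the smallest XIST difference. Y-linked genes near the floor do not decide it, and a breed difference in X-linked expression or in the timing of X inactivation stays open, as untested.

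The fourth pair also correlated less with the rest across probes, at 0.133 to 0.149, against 0.340 to 0.409 among the first 3 pairs. Array 7 of that pair stood apart from the other arrays of its orientation in Cy3, with 42.8% of probes above background and an SD of 42.0 over the negative control spots, and array 8 stood apart with 69.4%. The scan of array 7 as the whole cause is argued against by array 8, which alone correlated at 0.105 with the first 3 pairs, below the 0.280 of the weakest of arrays 1 to 6. The smaller X-linked difference as the cause is argued against by the correlations without X-linked probes, at most 0.142 for the fourth pair and at least 0.328 among the others. A pool of other embryos or a weaker amplification in that replicate stays open, as untested.

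In 8 other named genes 1 pair lay apart from the remaining 3, judged by its gap as a share of the range of the 4 values. The gap itself can be small, as for IFITM3, at -0.89 to -0.88 in the other pairs. TMEM254 had 1.17 in pair 2, KRT7 had -2.56 in pair 2, PNPLA6 had 0.60 in pair 3 and FAU had 0.87 in pair 3. In pair 4, IFITM3 had -1.06, ACADM had 0.81, FASN had -0.21 and SALL4 had -0.061. With XIST, 9 of 103 named probes stood out in this way, and 12 of all 119 groups of 4 values tested, where chance gives about 1 in 20, or 5.95. Many of these genes were named for a small p, which favours pairs close together, so that rate is approximate.

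The breed difference varied between the slides for 24 probes, among them the globins HBG, at -4.22, -3.84, 0.13 and 0.16 in the pairs, and HBB, at -2.24, -1.79, -0.02 and 0.05. Slide and replicate cannot be told apart here. Only 3 splits of the arrays keep each pair whole as the slides do, too few for a share under 0.05; all 3 gave as many, the highest other being 130, so that other groupings of whole pairs differed in more probes than the slides did.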

How the results depend on the processing

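The alternatives chosen only after the data were seen were normexp against negative controls, leaving out X-linked genes and each slide alone; all others were planned. The count of probes past the threshold between the breeds, 0 on pair means, was 48 for probes above background in both channels of all 8 arrays, where fewer probes were tested, 1209 with the pair as a random replicate block and 2054 with 8 arrays as independent samples, which have more residual degrees of freedom. In the restricted test the moderated SE changed as well, for BCAP31 (EMBV3_32173) from 0.069 to 0.105 and for XIST from 0.353 to 0.339. It ranged from 0 to 2 when each replicate was left out, the 2 being XIST (-3.39, adjusted p = 0.0204, from 0.000795 to 0.602 over its alternatives) and EMBV3_39949 without replicate 4. A threshold of 0.10 gave 189 probes, and an unadjusted p under 0.05 with at least 1.5-fold gave 1005. The other alternatives gave 0, as did the deposited table. Probes with an unadjusted p under 0.05, 4482 on pair means, numbered 2775 above background everywhere and 1958 as genes in place of probes, where fewer were tested, and 2421 on the second slide alone. The share of them higher in Holstein, 47.4%, was 62.9% under median centring, and the cause was not tested. Gene lists past the threshold numbered 2 under median centring (oxidative phosphorylation, reversed to 0.13, and ribosomal proteins, reversed to 0.15), 2 with slide as a fixed term (heat shock and erythrocyte), and 0 to 1 when a replicate was left out, heat shock passing without replicate 1; the cause was not tested. With an estimated correlation none of these calls held (adjusted p = 0.866 to 0.961). Probes differing between slides fell from 24 to 12 with the block.

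Of 2028 values of the 103 named probes under alternatives, 1920 kept direction and side of the threshold, 104 passed it in the same direction and 4 were reversed: SRY (-0.017 to 0.089 when a replicate was left out, negative without replicate 4, and -0.028 on the first slide alone) and, on the second slide alone, HBB at 0.017 and HBG at 0.15. Of 30 lists, 7 kept the sign of their median throughout. The X-linked minus autosomal median lay between -0.21 and -0.10 over 7 alternatives for background correction, normalization and value source. Aquantile scaling left log ratios as they were, and pairing by neighbouring array numbers gave the same pairs as the main matching. Both are among the alternatives counted here, could not differ and say nothing of stability. Lists were not run with the random block or the intensity trend. Medians of 1.24 to 1.34 times the negative controls mean that small differences of dim probes were not detectable.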

Other observations

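The listing of the largest differences, the shares of probes without a symbol and the limit to splits that part all pairs were chosen only after the result was seen. The largest differences over all probes were mostly higher in Jersey, 12 of 15, and 4 of the 15 were X-linked. Nidogen 1, NID1, a basement membrane protein, stood at -3.26 ± 0.74, with pairs from -5.36 to -1.30. The immune GTPase GIMAP4 had -2.99 ± 0.35, and the X-linked meiosis gene TEX11 had -2.83 ± 0.31, with Holstein signal above background on 4 of 8 arrays. The glutathione transferase GSTO1 (-2.16 ± 0.35), the trophoblast Kunitz domain protein TKDP1 (-2.11 ± 0.40) and ULBP21 (-2.07 ± 0.49), a ligand of natural killer cell receptors, were also higher in Jersey in 4 of 4 pairs. The X-linked cancer-testis genes PAGE4 and CT47B1 stood at -2.05 ± 0.69 and -2.00 ± 0.30, PAGE4 with -4.74 in pair 3 and -1.47 to -0.64 in the others. CT47B1 had Holstein above background on 1 of 8 arrays, so the size of its ratio depends on the floor. All but PAGE4 passed with the pair as a random block, and none passed on pair means over all kept probes, where adjusted p ran from 0.0885 to 0.296. Among probes above background everywhere, GIMAP4 passed (adjusted p = 0.0438).

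Probe EMBV3_39949, which the annotation gives no symbol, had a ratio of 4.94 ± 1.06 (adjusted p = 0.174). Its Jersey signal was above background on 3 of 8 arrays, so the size of the ratio depends on the floor. It had 6.64, 6.20 and 6.16 in the first 3 pairs and 0.75 in the fourth; without replicate 4 it passed (adjusted p = 0.0083), with the same limit. EMBV3_29688, also without a symbol, had 3.05, 3.31 and 3.64 in the first 3 pairs and -0.12 in the fourth. Probes without a symbol made up 72 of the 116 higher in Jersey at a threshold of 0.10 (62.1%), 24 of the 73 higher in Holstein (32.9%) and 47.9% of those tested. With the random block they were 53.7% of probes higher in Jersey and 33.2% of those higher in Holstein. Of the 43 probes higher in Jersey when only probes above background everywhere were tested, 37 had no symbol, with ratios from -2.19 to -1.01, while 40.3% of the 14019 tested lacked one.

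Other splits of the arrays into equal groups bear on the counts. Of 35 splits, 8 part all 4 pairs as the breeds do, too few for a share under 0.05. Among these, the random-block fit gave 1209 probes for the real split, met by 1 of 8, and at most 205 for the others; independent arrays gave 2054, met by 1 of 8, and at most 443; and the dye effect 5400, met by 1 of 8, and at most 0. Both 205 and 443 came from the split that turns the fourth pair. The splits that part fewer pairs gave 0 probes in both breed fits and at most 66 for the dye effect. On pair means there are 8 ways of turning the signs, again too few: the count of 0 past the threshold was met by 8 of 8, the highest other being 0, 4482 probes of unadjusted p under 0.05 were met by 1 of 8, the highest other being 2627, and 0 lists were met by 8 of 8, the highest other being 2.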
